A study of Homo sapiens with 6 samples.

How the data were processed

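Total RNA of HEK293 cells was measured in 6 libraries, 3 with a control siRNA and 3 with an siRNA against ZC3H4. Per the labels' protocols, RNA was extracted with Trizol, and 200 ng went into a stranded library kit for total RNA from Illumina. The deposited table lists 57773 genes with Ensembl IDs, symbols, biotypes, gene lengths and, for every library, a read count and an RPKM value. Per the submitters' processing notes, STAR and featureCounts were used, with GRCh37 and hg19 as genome builds; versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited counts are whole numbers, not normalized.

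The columns of the table name siCon with the numbers 2, 5 and 8 and siC19 with the numbers 3, 6 and 9. C19orf7 is an older name of ZC3H4 in the gene table used here, and siZC3H4 is the only siRNA besides siCon in the labels. The siC19 columns were therefore assigned to siZC3H4. None of these numbers is a replicate number of the labels, so the libraries are called by the table's own numbers and were not paired. The 6 RPKM columns were not used here. Start and end positions are printed as the table gives them, and they belong to the first exon listed for a gene: the interval was shorter than the gene's length in 35340 genes and longer in 0.

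Because the strand setting was not stated, it was checked on the counts. Of 217 noncoding genes whose exons lie wholly inside exons of a coding gene on the other strand, 177 (81.6%) had counts, and their median read density was 0.00296 of that of the coding gene. Reads of the 2 strands were thus counted apart. Pairs of libraries within a group differed by more than sampling noise, with chi-square values of 13.7 to 58.8 per gene, so each library was counted once.

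Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr at its defaults, which left 23145 genes, the quasi-likelihood test of siZC3H4 against siCon without covariates, and Benjamini-Hochberg adjustment, with 0.05 as threshold. The SE of a log2 fold change was taken as its size divided by the root of the F statistic. Levels are TMM-scaled CPM computed from the deposited counts, given as mean ± SD over 3 libraries. A run on simulated counts with the means and library sizes of siZC3H4 against siCon tested 22691 genes. It recovered 76 of 95 genes changed 2-fold (80.0%) and 56 of 95 changed 1.5-fold (58.9%), with 6 false calls. Far fewer genes were changed in this run than were called in the real data, so these rates need not hold there.

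The design, the rule for the genes named and 21 gene lists were fixed before the data were examined. Named were ZC3H4 and the other members of its list; the 8 coding genes with the largest change upward and the 8 downward, and the 6 upward and 6 downward among other genes, each with an adjusted p under 0.05, at least 1 CPM on average and no overlap between groups; and up to 4 members of each list with the smallest adjusted p, not all of which are printed. A coding gene that this rule names is not reported here. The lists were the ZWC complex with SPT5-SPT4, PNUTS and SETD1, Integrator, nuclear exosome, cleavage and polyadenylation, pausing and elongation, and RNA interference. Further lists were p53 targets, ATF4 genes, interferon, NF-kB, immediate early genes, histones, G1/S, G2/M, cholesterol, HOX and snoRNA hosts. The last were abundant nuclear or well studied long noncoding RNAs, mitochondrially encoded mRNAs and markers of other cell types. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and beside it with an estimated correlation and with fry.

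Gene classes were compared with coding genes by Fisher's exact test, two-sided. Classes by symbol were the planned choice where no annotation of the table's own build was at hand. The annotation used here, GENCODE 29, is on another build, so no coordinate of it is printed; it gave strand and neighbours for 52338 of the table's IDs (90.6%). Divergent noncoding genes start from 1000 bp upstream to 500 bp downstream of the start of a coding gene on the other strand, intergenic ones lie at least 5000 bp from any coding gene, and downstream tandem genes start within 10000 bp after the end of a coding gene on the same strand. Matching of coding genes on mean log2 CPM allowed a difference of 0.1. Bootstrap intervals rest on 2000 draws.

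Alternatives were RLE scaling, upper-quartile scaling, scaling on coding genes, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 3 libraries, other windows for the positional classes and each library left out in turn. Added after the data were seen were limma on log2(RPKM + 0.1) and log2(RPKM + 1), with RPKM recomputed from the counts and lengths, libraries thinned to the smallest total of 56494612 counts, a block for column sets, biotype and positional classes, and 15 gene families. Totals ran from 56494612 to 107301325 counts per library, so that a gene at 1 CPM rests on about 56.5 counts in the shallowest library, and precision is lower for genes under that level.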

Results

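Strand-specific RNA-seq of total RNA was analysed in 6 libraries of HEK293 cells, an established human embryonic kidney cell line. The cells of 3 libraries had received a control siRNA (siCon) and those of the other 3 an siRNA against ZC3H4 (siZC3H4). ZC3H4 encodes a zinc finger protein that works with WDR82 in restraining noncoding transcription. The title of the study is about a complex called ZWC, phosphorylation of the elongation factor SPT5 and divergent antisense RNA, so the comparison of siZC3H4 with siCon asks which RNAs change when ZC3H4 is depleted and whether antisense RNAs are among them. Gene counts summed to 74833373, 85083045 and 107301325 in siCon libraries 2, 5 and 8, and to 61496693, 56494612 and 63445199 in siZC3H4 libraries 3, 6 and 9, where the library numbers are those of the deposited table. Every siCon library was therefore deeper than every siZC3H4 library. Spearman correlations of log2 CPM, counts scaled to library size, were 0.992 to 0.996 within groups and 0.972 to 0.977 between groups, and the first principal component, with 72.1% of the variance, separated the groups.

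ZC3H4 itself, the target of the siRNA, was lower in all 3 siZC3H4 libraries than in any siCon library. It stood at 47.9, 34.5 and 35.8 CPM in siCon libraries 2, 5 and 8 and at 32.5, 25.2 and 25.1 CPM in siZC3H4 libraries 3, 6 and 9. Its level was 39.4 ± 7.42 CPM in siCon and 27.6 ± 4.21 CPM in siZC3H4 (mean ± SD, n = 3 each), a log2 fold change of -0.51 (SE 0.138, edgeR adjusted p = 0.0122). ZC3H4 (ENSG00000130749) lies on chromosome 19 of GRCh37, where the first exon listed for it spans positions 47567444 to 47571126. Of its partners in the complex, WDR82 rose by 0.40 on the log2 scale (SE 0.062, edgeR adjusted p = 0.00053) and CSNK2A2, a catalytic subunit of casein kinase 2, rose by 0.37 (edgeR adjusted p = 0.0010). The other catalytic subunit, CSNK2A1, went down from 150 ± 4.81 to 95.3 ± 4.08 CPM (n = 3 each), a log2 change of -0.66 (edgeR adjusted p = 2.5e-05). The regulatory subunit CSNK2B (log2 fold change -0.11) and the SPT5-SPT4 genes SUPT5H (-0.00) and SUPT4H1 (0.09) did not pass the test. The call for ZC3H4 was lost without siZC3H4 library 9, with a log2 change of -0.46 and an edgeR adjusted p of 0.0564, while the log2 change stayed negative in every setting run, from -0.66 to -0.35.

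**Figure D1:**
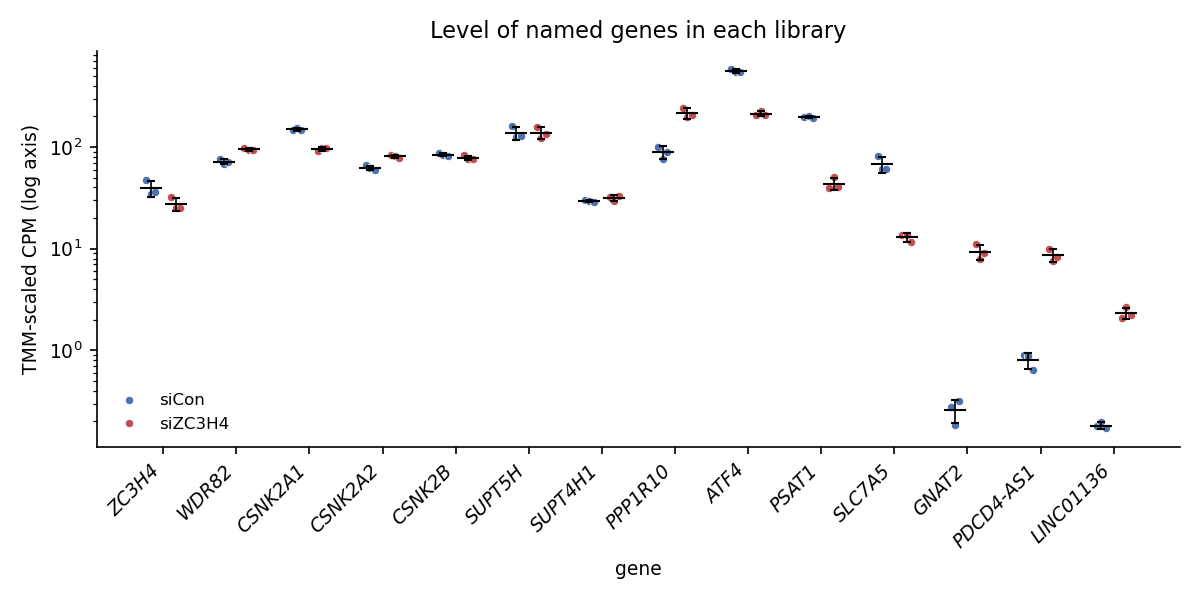
TMM-scaled CPM of named genes on a log axis, one point per library, with the mean and SD of each group of 3 libraries as a black bar with whiskers. ZC3H4 lay at 39.4 CPM in siCon and 27.6 CPM in siZC3H4, while GNAT2 went from 0.258 to 9.38 CPM and PSAT1 from 196 to 43.5 CPM.

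Among coding genes with at least 1 CPM on average and no overlap between groups, those nearly silent in control cells had the largest fold increases. Ranking by fold favours genes with a low control level. GNAT2, the cone transducin alpha subunit, went from 0.258 ± 0.0667 to 9.38 ± 1.60 CPM (n = 3 each), a log2 fold change of 5.16 (SE 0.205, edgeR adjusted p = 4.7e-07); it lies on chromosome 1, with its first listed exon at 110145889 to 110146166 (GRCh37). AC074212.3, WDR87 and INHBC, an inhibin beta subunit gene, rose by 4.61, 4.47 and 4.36 on the log2 scale from 0.117, 0.107 and 0.166 CPM in siCon. GNAT2, AC074212.3, WDR87, INHBC and BTK overlap the region upstream of an expressed coding gene on the other strand (AMPD2, FBXO46, SIPA1L3, R3HDM2 and RPL36A). BTK, a tyrosine kinase of B cells, rose by 3.51, APOBEC3H by 3.49, the myosin gene MYO1F by 3.36 and STPG2 by 3.35. Under the same limits, the largest decreases among coding genes were in TMEM154 (log2 fold change -3.13), ABCA10 (-3.10), the myosin heavy chain gene MYH15 (-2.71) and SLC7A5 (-2.38). SLC7A5, a large neutral amino acid transporter, went down from 67.4 ± 11.8 to 13.0 ± 1.27 CPM (n = 3 each, edgeR adjusted p = 1.3e-06). RHEBL1, the cell cycle inhibitor CDKN2D and the protease gene CTSK fell by 2.37, 2.33 and 2.21 on the log2 scale.

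Over all genes, 10623 of 23145 tested genes (45.9%) differed between the groups at an edgeR adjusted p under 0.05, 5472 of them higher and 5151 lower in siZC3H4. Changes of at least 2-fold were mostly upward, with 2088 genes higher and 726 lower. The 3 libraries of one group lay wholly on one side of the other group's 3 in 12694 genes (54.8%), where chance gives 10%. The higher share of the called genes was 51.5%, against 58.4% with upper-quartile scaling and 58.3% with scaling on coding genes. It was 64.5% when log2(RPKM + 0.1) recomputed from the counts was tested with limma and 64.7% with log2(RPKM + 1). Among coding genes, 3342 were higher and 4380 lower in the main fit. With upper-quartile scaling these counts were 3878 and 3743, and with scaling on coding genes 3861 and 3749. The balance between higher and lower coding genes thus depended on the scaling. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

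RNAs antisense to coding genes rose far more often than coding genes. Of 399 tested noncoding genes with an antisense name (ending in -AS or -DT), 219 (54.9%) were higher and 28 (7.0%) lower in siZC3H4, against 22.4% higher and 29.4% lower among 14916 coding genes. The odds ratio for being higher was 4.21 (Fisher's exact test, two-sided, p = 1.9e-43). PDCD4-AS1, on chromosome 10 with its first listed exon at 112629626 to 112630196, rose from 0.806 ± 0.146 to 8.63 ± 1.24 CPM (n = 3 each), a log2 fold change of 3.44 (SE 0.168, edgeR adjusted p = 1.0e-06). LINC genes, long intergenic RNAs by name, were higher in 63 of 172 (36.6%) and lower in 14 (8.1%; Fisher's exact p = 3.0e-05 for the higher share). Against coding genes matched on mean log2 CPM, of which 26.2% were higher, the difference for LINC genes was small (Fisher's exact p = 0.0480), while for antisense names the matched share was 31.3% (Fisher's exact p = 2.4e-11). LINC01136, on chromosome 1 with its first listed exon at 203267886 to 203269775, rose by 3.67 on the log2 scale to 2.33 CPM. By position it is a divergent noncoding gene, not an intergenic one. Host genes of small RNAs went the other way in number, with 4 of 24 higher and 9 lower, but the higher share was not distinguishable from that of coding genes (Fisher's exact p = 0.629). The remaining noncoding genes were higher in 24.2% of 7634 and lower in 9.4% (Fisher's exact p = 0.00325), and several settings ended or turned this small excess.

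The biotypes in the deposited table and the position of genes relative to coding genes, both taken up after the files were seen, gave the same order. Genes of antisense biotype were higher in 819 of 1662 (49.3%) and lower in 91, with a median log2 fold change of 0.64, and lincRNA genes were higher in 603 of 1558 (38.7%) and lower in 140. Pseudogenes were split, with 399 higher and 371 lower of 2732, and snoRNA genes were higher in 15 and lower in 30 of 361. Noncoding genes that start divergently from a coding promoter were higher in 551 of 952 (57.9%) and lower in 34, with a median of 0.75 and an odds ratio of 4.67 against coding genes (Fisher's exact p = 2.2e-109). Coding genes matched on mean log2 CPM were higher in 25.9% for divergent genes, 27.4% for the antisense biotype and 27.3% for lincRNA. With no filter on low counts, the higher share was below that of coding genes for LINC names (16.7%), lincRNA (16.3%) and genes that overlap a coding gene on the other strand (14.6%). Noncoding genes that overlap a coding gene on the other strand without sharing its promoter were higher in 35.9% of 1605, intergenic ones in 22.7% of 1935 and those just downstream of a coding gene on the same strand in 13.2% of 439. Fisher's test treats genes as independent; with a correlation between genes estimated from the data, the camera p was 0.0228 for the antisense biotype, 0.107 for lincRNA, 0.0613 for divergent genes, 0.0753 for antisense names and 0.0704 for LINC names.

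**Figure D2:**
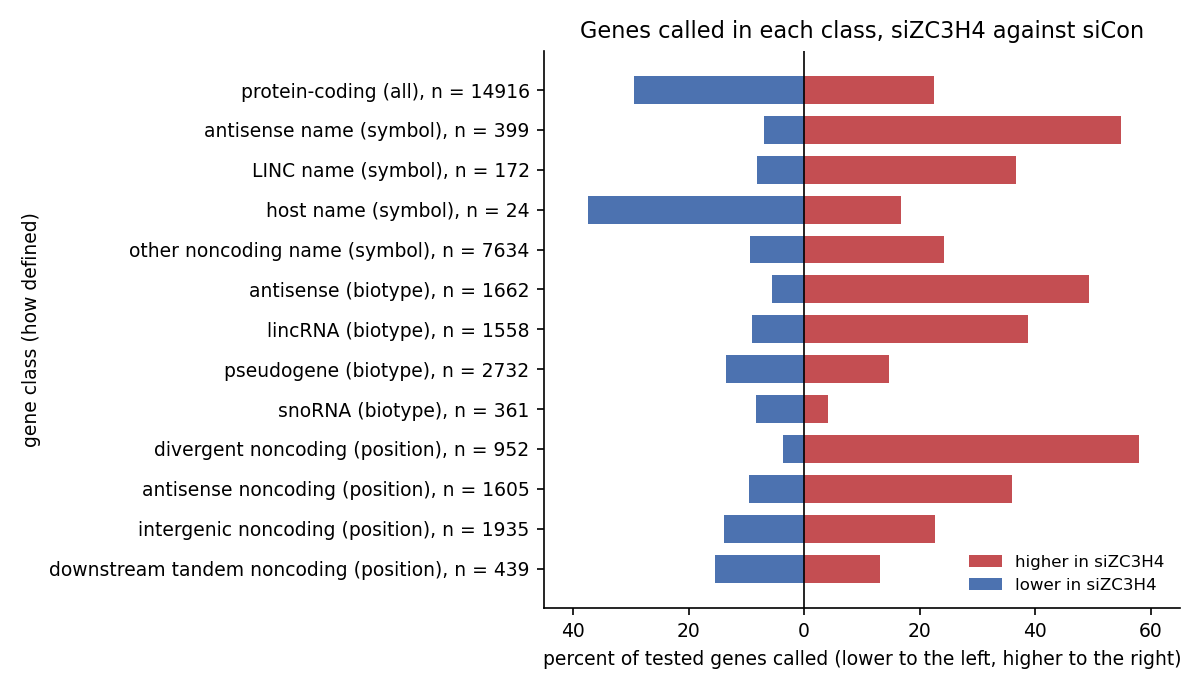
Percent of tested genes called higher (right, red) and lower (left, blue) in siZC3H4 at an edgeR adjusted p under 0.05, for gene classes defined by symbol, by biotype in the table or by position. Divergent noncoding genes were higher in 57.9% and antisense-named genes in 54.9%, against 22.4% of all coding genes.

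Among other noncoding genes, the lincRNA RP1-150O5.3 rose by 3.97 on the log2 scale, from 0.342 to 5.28 CPM. RP5-858B6.3 (3.64), of antisense biotype but intergenic by position, the pseudogene GTF2IRD1P1 (3.45) and the lincRNA RP11-428J1.5 (3.42) also rose. Outside coding genes, at 1 CPM or more on average, the largest decrease was in the pseudogene RP13-33H18.1 (-3.91). Next came the lincRNAs RP1-153G14.4 (-2.12) and SOX21-AS1 (-1.99), and the pseudogenes ATF4P4 (-1.88), ZNF101P2 (-1.66) and VN1R83P (-1.64). SOX21-AS1 thus fell, from 6.82 ± 0.355 to 1.72 ± 0.514 CPM (n = 3 each), although it carries an antisense name. Values of pseudogenes are uncertain, since reads can be shared with their parent genes, as between ATF4P4 and ATF4.

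Coding genes that share a promoter with a divergent RNA that rose were called about as often as other coding genes. Whether the members of a pair change together was not tested. Of the 551 divergent noncoding genes that rose, with a median log2 fold change of 1.23, the coding partners tested numbered 533, and 120 of these were higher, 169 lower and 244 not called. Their median log2 fold change was -0.05 (95% bootstrap interval -0.09 to -0.02), and 22.5% were higher and 31.7% lower, against 22.4% and 29.3% of 14384 other coding genes. Over all tested genes, upper-quartile scaling shifted log2 changes by a median of 0.051, so the sign of so small a median may depend on the scaling. PDCD4, the partner of PDCD4-AS1, had a log2 fold change of -0.17, and KANSL3 fell by 0.56 on the log2 scale while FER1L5, listed as a pseudogene and starting divergently from it, rose by 3.40. TMEM254-AS1 rose from 2.17 ± 0.458 to 13.4 ± 0.607 CPM (n = 3 each; log2 fold change 2.62) beside TMEM254, which rose by 0.37. BTG2, beside LINC01136, rose by 1.01 on the log2 scale. Where the partner had at least 5 CPM in siCon, 504 of 846 divergent genes (59.6%) were higher, against 33 of 76 (43.4%) where it had less (odds ratio 1.92, 95% interval 1.16 to 3.19, Fisher's exact p = 0.0074, two-sided). These pairs and the examples FER1L5, KANSL3, TMEM254-AS1, TMEM254 and PDCD4 were chosen after the values were seen. In the comparison by partner level, the divergent genes were not matched on their own level, which affects how easily they are called.

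**Figure D3:**
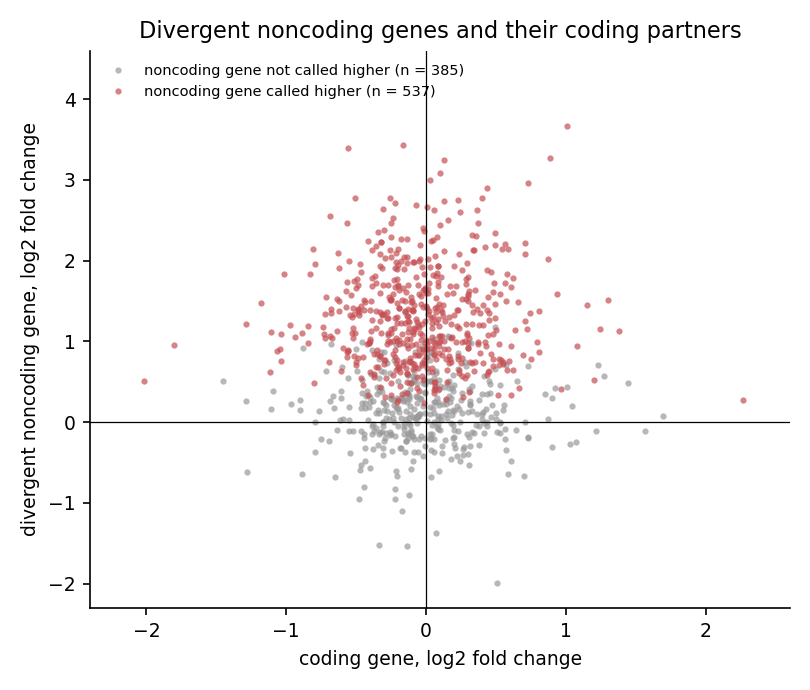
Log2 fold change (siZC3H4 against siCon) of 922 divergent noncoding genes on the vertical axis against that of the coding gene at the same promoter on the horizontal axis, one point per pair. The 537 noncoding genes called higher (red) lie above 0, while their coding partners lie on both sides of 0.

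Most listed genes of the integrated stress response fell. Of 17 genes driven by the transcription factor ATF4, 15 were lower and 0 higher, and as many were lower when adjusted over the list alone. ATF4 went from 562 ± 23.7 to 213 ± 10.7 CPM (n = 3 each), a log2 fold change of -1.40 (SE 0.067, edgeR adjusted p = 9.4e-07). The serine synthesis genes PSAT1 and PHGDH fell by 2.17 and 1.03 on the log2 scale and asparagine synthetase, ASNS, by 1.73. The camera adjusted p was 6.1e-08 with the preset correlation, and the adjusted p = 0.485 with an estimated correlation.

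Most listed cell cycle and histone genes were lower as well. Of 17 genes of the G1/S transition and DNA replication, 12 were lower and 0 higher (13 lower adjusted over the list alone). RRM2, a ribonucleotide reductase subunit, fell by 1.07 on the log2 scale, the transcription factor E2F1 by 1.02 and the helicase subunit MCM3 by 0.59; the camera adjusted p was 7.0e-05, and the adjusted p = 0.665 with an estimated correlation. Of 18 G2/M genes, 13 were lower and 1 higher, with the same counts adjusted over the list alone. The spindle factor TPX2 fell by 0.88, survivin (BIRC5) by 0.79, the kinase AURKB by 0.54 and cyclin B1 (CCNB1) by 0.44 (camera adjusted p = 9.2e-05; adjusted p = 0.643 with an estimated correlation). Of 20 replication-dependent histone genes, 14 were lower and 0 higher, also adjusted over the list alone, among them HIST2H2BE (-0.59) and HIST1H3B (-0.55); camera gave an adjusted p of 7.0e-05, and an adjusted p of 0.665 with an estimated correlation. Histone genes are near-identical copies that can share reads, so the values of single members are uncertain.

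Most listed noncoding host genes of small nucleolar RNAs fell. Of 12 tested, 10 were lower and 0 higher, also adjusted over the list alone. GAS5 went from 319 ± 47.5 to 163 ± 14.8 CPM (n = 3 each), a log2 fold change of -0.97 (edgeR adjusted p = 8.2e-05), and SNHG15, EPB41L4A-AS1, which also carries an antisense name, and SNHG1 fell by 0.78, 0.81 and 0.57 on the log2 scale. The camera adjusted p was 3.2e-05, and the adjusted p = 0.643 with an estimated correlation. Of 14 genes of cholesterol synthesis and uptake, 7 were lower and 0 higher, also adjusted over the list alone, led by the regulator SREBF2 (-0.97), INSIG1 (-0.64) and FDFT1 (-0.45); the camera adjusted p was 0.0020, and the adjusted p = 0.643 with an estimated correlation.

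Of 11 tested target genes of the inflammatory transcription factor NF-kB, 7 were higher and 2 lower, also adjusted over the list alone. The chemokine genes IL8 and CXCL1 rose by 3.19 and 3.29 on the log2 scale, to 3.24 and 1.10 CPM, while TRAF1 rose by 1.10 and RELB by 1.19. The camera adjusted p was 0.0407, and the adjusted p = 0.799 with an estimated correlation. The call was also lost in several settings, among them without siCon library 5 (adjusted p = 0.0536), with upper-quartile scaling (0.0542) and with scaling on coding genes (0.0527). Of 18 immediate early genes, 6 were higher and 2 lower (the same adjusted over the list alone), with EGR2 (1.87) and ZFP36 (0.86) among those that rose and NR4A1 (-0.71) among those that fell; the camera adjusted p was 0.266.

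Target genes of p53 and of interferon did not pass as lists. Of 23 p53 targets, 9 were higher and 5 lower (11 and 5 adjusted over the list alone), with CDKN1A, the cyclin-dependent kinase inhibitor p21, up by 1.23 on the log2 scale from 41.9 ± 7.62 to 98.0 ± 10.0 CPM (n = 3 each), DDB2 by 0.61 and RRM2B by 0.69 (camera adjusted p = 0.126). Of 17 tested interferon-stimulated genes, 3 were higher and 9 lower, also adjusted over the list alone. IFI44L (-1.32), IRF7 (-1.18) and IFIT1 (-0.85) fell and MX1 (1.06) rose (camera adjusted p = 0.104). With fry, which tests a list without comparing it to other genes, the adjusted p was 0.0160. The lists that passed camera with the preset correlation passed with fry as well.

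Genes for RNA processing and transcription complexes moved in both directions. In the PNUTS and SETD1 complexes, which also contain WDR82, 4 of 13 genes were higher and 2 lower, also adjusted over the list alone. PPP1R10, which encodes PNUTS, rose from 89.2 ± 12.1 to 215 ± 24.5 CPM (n = 3 each), a log2 fold change of 1.27 (SE 0.109, edgeR adjusted p = 1.5e-05), while ASH2L (-0.61) and WDR5 (-0.41) fell; the list's median was -0.07 and its mean 0.07, so they differ in sign (camera adjusted p = 0.899). Integrator genes were higher in 5 and lower in 3 of 15 (6 and 3 adjusted over the list alone), with INTS6 (0.73) and INTS3 (0.64) up and INTS10 (-0.42) down (camera adjusted p = 0.632). Nuclear exosome genes were higher in 1 and lower in 4 of 20 (0 and 2 adjusted over the list alone), with EXOSC5 (-0.77) and EXOSC2 (-0.36) among the latter (camera adjusted p = 0.632). Cleavage and polyadenylation genes were higher in 3 and lower in 8 of 17 (4 and 8 adjusted over the list alone), with NUDT21 (0.77) up and CSTF3 (-0.62) and the exonuclease gene XRN2 (-0.34) down (camera adjusted p = 0.266). Pausing and elongation genes were higher in 3 and lower in 9 of 23, also adjusted over the list alone, with CCNT1 at -0.54 (camera adjusted p = 0.162). RNA interference genes were higher in 3 and lower in 7 of 13, also adjusted over the list alone, with AGO2 (-0.71) down and TNRC6B (0.71) and DROSHA (0.50) up (camera adjusted p = 0.346). The list of the ZWC complex and SPT5-SPT4 had 2 higher and 2 lower of 7, also adjusted over the list alone (camera adjusted p = 0.899, and 0.836 without ZC3H4).

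The HOX genes, which lie in clusters rich in antisense transcripts, were higher in 7 and lower in 6 of 32, also adjusted over the list alone. HOXB7 rose by 0.82 on the log2 scale, and HOXA9 and HOXA5 fell by 1.10 and 0.77 (camera adjusted p = 0.632). Of 9 tested long noncoding RNAs, abundant nuclear or well studied ones, 2 were higher and 4 lower, also adjusted over the list alone. NEAT1 (-0.96) and OIP5-AS1 (-0.98) fell while MIAT (0.80) and KCNQ1OT1 (0.47) rose. The list's median of 0.04 and mean of -0.14 differ in sign (camera adjusted p = 0.645). Mitochondrially encoded mRNAs were higher in 3 and lower in 1 of 13 (3 and 0 adjusted over the list alone; camera adjusted p = 0.406). Of 16 markers of blood, liver, skin, fibroblast and muscle cells, 3 had enough counts to test, DES, COL1A1 and CD14. These did not pass the test, also when adjusted over the list alone, with edgeR adjusted p values of 0.125, 0.630 and 0.695 (camera adjusted p = 0.782).

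**Figure D4:**
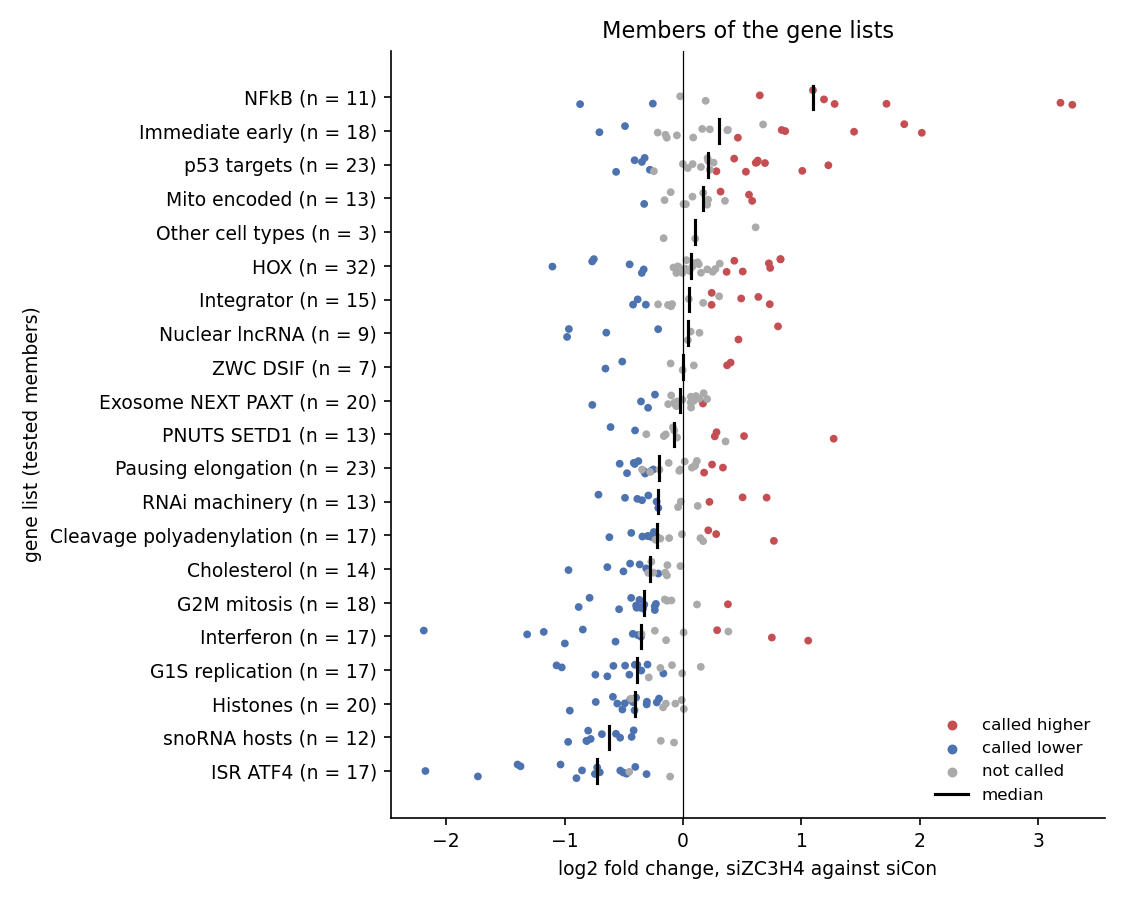
Log2 fold change (siZC3H4 against siCon) of each tested member of the 21 gene lists, one point per gene, red where called higher, blue where called lower and grey where not called, with the list's median as a black line. The ATF4 list had 15 of 17 genes lower and the NF-kB list 7 of 11 higher.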

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

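Recomputed RPKM, thinned libraries, the column block, the biotype and positional classes were chosen after the data were seen. Outside leaving out libraries, 1544 values under other settings were classed as the same, 36 lost a call, 8 gained one and 7 turned. With 1 library left out the counts were 880, 18, 1 and 1. A value classed as the same stayed on its side of the threshold, but values called in neither fit could change direction. Numbers of genes were classed as the same within 1.5 times. The number of changed genes stayed within 1.5 times of 10623 under every setting run, from 8390 without siZC3H4 library 9 to 13802 with the column sets as a block. The alternatives on deposited RPKM and on the labels' replicate number were not run. No paired analysis was possible because the columns carry no replicate number of the labels, in the sense of pairing by the labels, and a block on the table's own column numbers was run instead. The table's column sets 2-3, 5-6 and 8-9, entered as a block, had correlated deviations (0.33, 0.24 and 0.16), the highest for each library, which is a hint from the data and not from the design.

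ZC3H4 lost its call with recomputed RPKM + 0.1 (log2 change -0.41, adjusted p 0.0716) and + 1 (-0.35, adjusted p 0.0796), and ranged from -0.66 to -0.36 with 1 library left out; over all settings its adjusted p ran from 8.9e-09, with no filter on low counts, to 0.0796. With the column block its log2 change was -0.51 (adjusted p 2.5e-07), and the log2 ratio within the column sets was -0.56, -0.45 and -0.51. With an estimated correlation the adjusted p was 0.485 for ATF4 genes, 0.799 for NF-kB, 0.665 for histones and for G1/S, and 0.643 for G2/M, cholesterol and snoRNA hosts. NF-kB gave 0.0542 with upper-quartile scaling, 0.0527 with scaling on coding genes, 0.0582 with no filter, 0.139 with at least 1 CPM in 3 libraries, 0.0595 with the column block, and 0.0124 to 0.0536 with 1 library left out. Interferon passed with fry (0.0160), which does not compare a list with other genes. The lists that passed camera also passed with fry. The fry adjusted p was 0.0014 for ATF4 genes, 0.0020 for G2/M, 0.0174 for G1/S and 0.0273 for histones. For cholesterol, snoRNA hosts and NF-kB it was 0.0160 each. Pausing genes passed with no filter (0.0157) and ranged from 0.0305, without siZC3H4 library 3, to 0.334.

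With no filter on low counts, 16.7% of LINC names, 10.5% of other noncoding names, 16.3% of lincRNA and 14.6% of antisense noncoding genes were higher, below coding genes, and 7.1% of intergenic and 17.5% of tandem coding genes were higher; this setting adds genes with too few counts to be called. Other noncoding names also turned with upper-quartile scaling (26.0%), the column block (28.9%) and matched coding genes (24.2%), lost the call with scaling on coding genes (26.0%) and thinned libraries (23.6%), and ranged from 18.0% without siZC3H4 library 9 to 22.7% without siCon library 2. Intergenic genes were higher less often than coding genes with upper-quartile scaling and scaling on coding genes (24.0% each) and the column block (26.8%). The same held against matched coding genes (22.7% against 27.0%). Downstream tandem noncoding genes lost the call at 1 CPM in 3 libraries (20.5%). Downstream tandem coding genes lost it with a window of 5000 bp (20.7%) and matched coding genes (20.9%), and ranged from 16.1% to 21.9%. The cause was not tested for the changes without a stated one. Antisense-named and divergent genes kept their call in Fisher's test under every setting run for them.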

Other observations

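The tests of gene families, those against all tested antisense and lincRNA genes, those in thinned libraries and those on genes picked by the mean over all libraries were chosen after the values were seen. In 15 families of coding genes taken by symbol, Fisher's exact test was run for both directions against other coding genes, with Benjamini-Hochberg adjustment over the 30 tests. The families were not matched with other coding genes on expression level, and Fisher's test treats genes as independent. Aminoacyl-tRNA synthetases of the cytosol, which load amino acids onto tRNAs, were lower in 12 of 17 (70.6%) and higher in 3, against 29.3% lower elsewhere (adjusted p = 0.0031). NARS fell by 1.58 on the log2 scale, YARS by 1.29, from 276 ± 11.4 to 113 ± 6.51 CPM (n = 3 each), and IARS by 1.13, while RARS rose by 0.45. Kinesins were lower in 27 of 41 (65.9%) and higher in 3 (adjusted p = 2.0e-05), with KIF2C at -1.39 and KIF22 at -0.66, and KIF6 at 1.90.

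ZNF zinc finger genes moved the other way, with 178 of 466 (38.2%) higher and 50 lower, against 21.9% higher elsewhere (adjusted p = 1.0e-13). ZNF569 rose by 1.02 on the log2 scale, from 15.4 ± 1.22 to 31.1 ± 0.789 CPM (n = 3 each), ZNF480 by 0.93 and ZNF528 by 1.44. Members of this family are similar in sequence, so reads can be shared between them. The sign of the median of each of these 3 families was the same under RLE, upper-quartile and coding-gene scaling and with recomputed RPKM. Other families, taken by symbol alone, that passed in 1 direction were cytosolic ribosomal proteins (5.0% higher against 22.5% elsewhere, adjusted p = 0.000275), proteasome subunits (2.5% higher against 22.5%, adjusted p = 0.0044, or 0.0646 in thinned libraries) and protocadherins (11.3% lower against 29.4%, adjusted p = 0.0102). Other calls of these and further families depended on the setting. Ribosomal proteins were lower less often than other coding genes with upper-quartile scaling (11.2% against 25.2%, adjusted p = 0.0119), scaling on coding genes (11.2%, 0.0104) and recomputed RPKM + 0.1 (3.8% against 19.4%, 0.00052) or + 1 (3.8%, 0.00052), but lower more often with no filter (41.5% against 27.1%, 0.0173) and with the column sets as a block (52.5% against 38.4%, 0.0316). Protocadherins were higher more often with upper-quartile scaling (43.4%, adjusted p = 0.0228), scaling on coding genes (45.3%, 0.0104), no filter (36.5%, 0.0023), at least 1 CPM in 3 libraries (46.3%, 0.0116) and the block (45.3%, 0.0401), while the share was 15.1% and not called with RLE scaling and both RPKM settings. Kinesins (higher share) and proteasome, complex I, mitochondrial ribosomal, RNA polymerase and solute carrier genes likewise gained a call in some settings and not in others.

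Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 10623 genes and the highest of the others 0, and it called 1422 antisense and lincRNA genes higher against 0, so 1 of the 10 splits gave as many in both cases. Every other split puts siCon and siZC3H4 libraries on both sides, so a difference between the real groups raises the spread within its sides. The 0 calls of these splits therefore do not show what chance alone would give. For gene lists the real split called 7 and another split 10, and 3 of the 10 splits called at least 7. The splits took no account of the column sets 2-3, 5-6 and 8-9. The split that called 10 kept 2 with 3 and 5 with 6 on the same side. Apart from the real split, those with 1 column of each set on each side called 6, 4 and 7.

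For the rise of antisense and lincRNA genes, depth as the whole cause was argued against: with every library thinned to 56494612 counts, 86.8% of called antisense and lincRNA genes were higher, against 43.9% of called coding genes. Leakage at an unchanged rate from the overlapping coding gene would move both, but the partners of 592 antisense genes that rose had a median log2 change of -0.09 (95% bootstrap interval -0.13 to -0.05) against 1.22 for the antisense genes. Genomic DNA would add reads everywhere. Pooled, 379 olfactory receptor genes gained 0.00147 CPM per kb (-0.000998 to 0.00404, bootstrap over genes). Each siZC3H4 library lay above each siCon library (0.008 to 0.00897 against 0.0069 to 0.00723). The gain was far below the median of 0.612 for the genes that rose and 0.190 for all tested antisense and lincRNA genes. More nuclear RNA stays open. The 9 tested long noncoding RNAs were listed as abundant nuclear or well studied, so they need not all be nuclear. They went both ways, from -0.98 to 0.80, with a median change of 0.04 (-0.96 to 0.47). The bound planned from the genes that rose was too high, since all tested antisense and lincRNA genes had a median of 0.50. A changed rate of leakage, effects of the siRNA on other targets and depletion of ZC3H4 stay open too.

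The modest fall of ZC3H4, by 0.51 on the log2 scale, left open whether the siC19 columns name another gene once called C19orf. Of 61 other tested genes with such a name, 4 fell by more than 1 on the log2 scale with an edgeR adjusted p under 0.05, where the share over all tested genes gives 1.9 (exact binomial test, two-sided, p = 0.125). The lowest was DNAAF3 at -1.97, and C19orf12 went from 32.7 ± 0.344 to 12.3 ± 0.616 CPM (n = 3 each). The criterion set beforehand for another target, a fall of more than 1 with an adjusted p under 0.05 in another gene of such a name, was thus met. With 1.9 such genes given by the overall share, the criterion was likely to be met whatever the target. The count of such genes cannot decide the question either, since another target would need only 1 of them to fall. Another target is therefore not excluded by these values, which cannot decide it either way. The assignment of the columns rests on the labels, whose only siRNA besides siCon is siZC3H4, and on the older name of ZC3H4.

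Among 1854 tested coding genes under 1 CPM in siCon, 625 rose and 224 fell, an excess to which picking genes by a low siCon level contributes. Picked by the mean over the 6 libraries instead, 481 of 1756 rose and 269 fell, so that 64.1% of called genes were higher (95% exact binomial interval 60.6 to 67.6) against 43.3% of all called coding genes, which argues against this selection as the whole cause. Thinning argues against depth as the whole cause, since 88.6% of those that rose were still called higher in thinned libraries. A candidate explanation is antisense transcription that starts at a neighbouring active promoter: of 240 genes that overlap the 5000 bp upstream of a coding gene on the other strand with at least 5 CPM in siCon, such as GNAT2 beside AMPD2, 139 (57.9%) rose, against 448 of 1493 others (30.0%), leaving out 121 genes whose position was not known (odds ratio 3.21, 95% interval 2.41 to 4.29, Fisher's exact p = 1.8e-16). Picked by the mean over the 6 libraries, the odds ratio was 2.76 (2.01 to 3.78, Fisher's exact p = 1.6e-10), and gene counts cannot show where along a gene the reads lie.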
